A study of Mus musculus and Homo sapiens with 12 samples.

How the data were processed

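The samples are ChIP-seq libraries of mouse NPC and OPC cultures and of a human NPC line. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared, and CTCF or H3K27ac was precipitated with a named antibody; mouse NPC grew with EGF and FGF2 and OPC with PDGFB and FGF2. The titles call the mouse cells NPC derived from embryonic stem cells, while the cell type label of the OPC samples gives OPC; groups follow the sample names and that label. Per the submitters' processing notes, BWA 0.7.4 and Picard 2.9.2 were used with builds hg19 and mm10. The peak caller, its threshold and any control library are not given in the sources used here. The deposited files are 1 peak list per sample, with position, name, a score and a strand sign. The deposited score is 1 in every line of every file, so it carries no peak strength. The authors' CTCF peaks have 1 fixed length per list, apart from a few of 287 bp in OPC_Insulator: 227 bp in NPC, 193 bp in OPC, 267 bp in OPC_NT and 297 bp in OPC_Insulator. H3K27ac regions vary from 501 bp upward. Lines of the CTCF lists run with the number in the peak name (Spearman's rho across peaks 0.849 to 0.913), and H3K27ac lists run from long to short regions (rho -0.953 to -0.949). Places in a list were used only to describe or divide that list. Depth is unknown for all 7 libraries.

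Groups were taken from the labels, 1 library each, so no test between groups was run and no p-value across peaks or genes is given. Comparisons among mouse lists used peaks on chromosomes 1 to 19 and X, which left out 4 to 71 peaks per list; the comparison of human with mouse used both whole lists. Lists were compared with bedtools 2.31.1 (Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9) with an overlap of at least 1 bp, beside 100 rotations of the peaks along their chromosomes. Shares have 95% exact binomial intervals. Genes came from a RefSeq table of assembly GRCm38.p6, the assembly of mm10, with 21631 protein-coding genes on these chromosomes; at most 0.0119% of the peaks of a list lay beyond the last gene of their chromosome. The table used gives gene starts and ends without strand or exons. The planned windows around the transcription start were therefore replaced by windows around both gene ends: 1 kb for a region at a gene and 20 kb for the acetylated length. Positions are described as within or outside annotated gene spans. Peak coordinates are given from 1. Of 304 genes in 24 lists written before the data were examined, 303 were found, and Nespas was not. A list's mean difference was placed among 10000 random lists of the same size, matched gene by gene on covered length in 20 bins. It was placed again among random lists from the same chromosomes, matched on covered length in fewer, coarser bins. This describes these libraries only.

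Named items followed rules fixed before the data were examined. For H3K27ac they are the 12 genes with the largest difference each way among those with a region at an end in 1 cell type alone (1 per 100 kb), list members whose state differs, and the genes of the Pdgfra and Cdkn2a loci. For CTCF they are the 12 peaks earliest in each list without a peak of the other list within 1 kb, peaks in 1 list alone within 20 kb of an oligodendrocyte progenitor or stem list gene, the sites from Scfd2 to Kit, and the 12 earliest OPC_NT sites shared with NPC and OPC without an OPC_Insulator peak within 1 kb. The rule ranked peaks by score; line order took its place. Genes named elsewhere as examples were chosen after their values were seen. Single values of a few list members are not reported here; the list counts and means include them. Overlap, covered length and list percentiles were tested on simulated data. All 13983 planted shared peaks among 19834 simulated from NPC CTCF peaks were recovered. They had been shifted by less than 1 peak length, so this checks the procedure only. With 100 simulated lists of 15 genes each, drawn for the H3K27ac comparison over 21631 genes, 5% of lists without a difference, 44% of those with 1 kb added per gene, 90% with 2 kb and 100% with 4 kb passed the 95th percentile. Each gene had independent normal noise with an SD of 2.5 kb at any covered length, so the 5% follows from the setting. Real neighbouring genes can share regions, so these rates need not hold for the real lists. Alternatives were another overlap rule, other windows, all sequence names, and parts of the lists by line order. The 5 OPC H3K27ac samples without a list were not analysed here.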

Results

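The series profiles CTCF, the DNA-binding protein that marks insulators and chromatin loop anchors, and H3K27ac, the histone mark of active promoters and enhancers, by ChIP-seq in cultured neural cells. Of 12 samples in 12 groups, 7 had a peak list that was analysed here. They are 4 mouse CTCF lists (NPC, OPC, OPC_NT and OPC_Insulator), 2 mouse H3K27ac lists (NPC and OPC) and 1 human NPC H3K27ac list. NPC are neural progenitor cells, and OPC are oligodendrocyte progenitor cells, the dividing precursors of the myelinating cells of the brain. The other 5 samples, all mouse OPC H3K27ac, were not analysed here. Each group is 1 library, so no difference below has a replicate check. The 95% exact (Clopper-Pearson) intervals cover counting error only. Read depth is unknown. The CTCF lists held 88586 peaks in NPC, 76774 in OPC, 77853 in OPC_NT and 48497 in OPC_Insulator. The H3K27ac lists held 41874 regions covering 70.8 Mb in mouse NPC, 38325 covering 68.8 Mb in mouse OPC and 56154 covering 121.9 Mb in human NPC. Comparisons among mouse lists used chromosomes 1 to 19 and X, and the comparison with human used whole lists. Every peak carries the same score, 1. The place of a line in its list therefore served as the ordering. What the authors ordered by is not given in the sources used here. Mouse positions are on build mm10.

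The comparison of CTCF in NPC and OPC asks how far CTCF occupancy differs between the progenitor and the oligodendrocyte-lineage state. Most sites were shared. An OPC peak overlapped 67840 of 88532 NPC peaks (76.6%, interval 76.3 to 76.9), and an NPC peak overlapped 67840 of 76703 OPC peaks (88.4%, interval 88.2 to 88.7). Peaks rotated along their chromosomes overlapped in 1.29% on average over 100 rotations. The sites in 1 list alone came mostly from the later lines: 0.124% of the first 10% of the NPC list had no OPC peak, against 75.2% of the last 10%. The earliest NPC peak without an OPC peak within 1 kb lay on chromosome 19 from 59454274 to 59454500, 4.3 kb from Emx2, a forebrain patterning factor. Other early NPC peaks of this kind lay 1.8 kb from an end of the Wnt ligand gene Wnt11, 3.4 kb from the stem cell receptor gene Lgr6, and near Sfi1, Klrb1b, Slc48a1, Clip2, Ddx52, Nxnl1, Wwox, Rngtt and Bcam. The early OPC peaks without an NPC peak within 1 kb included a site 18.5 kb from the T-box gene Tbx5 and sites within the annotated spans of Arhgdia, Znhit1, Asic2, Tiam2 and the neuronal adhesion gene Tenm4. The others lay between genes, and the nearest gene ends were those of Gm17019, Ly6c2, Txnrd3, Bco2, Tmem200c and Tmem132e.

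Within 20 kb of an end of the 20 oligodendrocyte progenitor list genes, 7 of 78 NPC peaks (8.97%) were in NPC alone. Of 82 OPC peaks there, 11 (13.4%) were in OPC alone. Over all peaks compared, these shares were 23.4% and 11.6%. Sox10, the transcription factor of the oligodendrocyte lineage, had 2 peaks in OPC alone (chromosome 15, 79148060 to 79148252 and 79166916 to 79167108), as did Sox8. Olig2, Vcan, Cacng4 and Pdgfra, the PDGF receptor of oligodendrocyte progenitors, had 1 each, and Pcdh15 had 1 in each list. The Pdgfra peak (75143865 to 75144057) had no OPC_NT peak but overlapped an OPC_Insulator peak (75143830 to 75144126). Its centre lay 585 bp from that of an NPC peak. The other OPC-alone peaks named here were not set against OPC_NT or OPC_Insulator. A difference between the cell types is thus not shown for them. Nkx2-2 had 3 peaks in NPC alone and 1 in OPC alone; 1 NPC peak (chromosome 2, 147178189 to 147178415) and the OPC peak (147177799 to 147177991) lie side by side without overlap. Cspg4, Ptprz1 and Matn4 each had 1 peak in NPC alone. Around the 20 genes of the neural stem list, 17 of 76 NPC peaks were in NPC alone (22.4%). Of 69 OPC peaks, 9 were in OPC alone (13.0%). Both shares lay near those over all peaks. Hes1, an effector of Notch signalling, had 3 of its 4 NPC peaks in NPC alone, and Notch1 3 of 9, with 1 OPC peak in OPC alone. Msi1 had 3 peaks alone in each list, Emx2 had 2 in NPC alone and 1 in OPC alone, and Sox3 had 1 in NPC alone and 2 in OPC alone. Sox2, Vim, Lhx2, Id1 and Nr2f1 had 1 each in NPC alone, and Pax6 and Sox1 had 1 each in OPC alone. Most of these peaks stand late in their lists; the 4.3 kb Emx2 site and the side-by-side Nkx2-2 pair stand early. Some had a peak centre of the other list within 1 kb: 1 of 7 NPC-alone and 4 of 11 OPC-alone peaks of the progenitor list, and 3 of 17 and 2 of 9 of the stem list, among them side-by-side pairs at Msi1 (568 bp apart) and Notch1 (654 bp).

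The share of unshared CTCF peaks differed between whole chromosomes. NPC peaks without an OPC peak made up 33.4% on chromosome 16, 33.4% on chromosome 18, 33.2% on X and 33.1% on chromosome 12, against 15.4% on chromosome 15 and 16.4% on chromosome 11. The OPC peaks without an NPC peak went the other way, with 5.54% on X and 15.7% on chromosome 11. Hes1 and Olig2 lie on chromosome 16, Sox3 on X and Sox10 on chromosome 15. On the 10 chromosomes whose ratio of OPC to NPC peak number lay near the median, 79.3% of NPC peaks had an OPC peak and 87.9% of OPC peaks had an NPC peak.

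**Figure D1:**
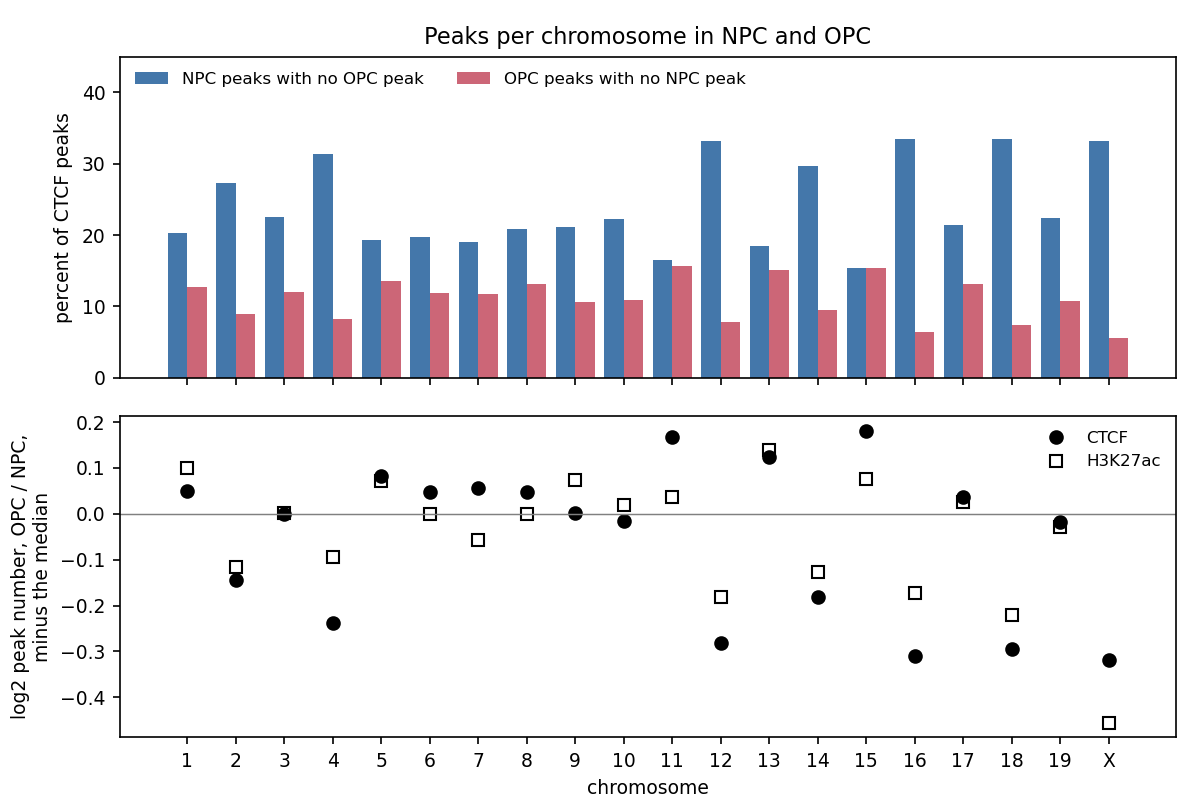
Upper panel: percent of the CTCF peaks on each chromosome without a peak in the other list, NPC in blue and OPC in red. Lower panel: log2 ratio of the number of peaks in OPC to that in NPC per chromosome, minus the median over chromosomes, for CTCF (filled circles) and H3K27ac (open squares); chromosomes 12, 16, 18 and X lie lowest for both, X at -0.32 for CTCF and -0.45 for H3K27ac.

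The lists of OPC and OPC_NT come from the same cell type and show how far a pair of such lists differ, although the labels do not make them replicates. OPC_NT peaks overlapped 66965 of 76703 OPC peaks (87.3%, interval 87.1 to 87.5), and OPC peaks overlapped 66965 of 77783 OPC_NT peaks (86.1%, interval 85.8 to 86.3). Rotated peaks overlapped in 1.45% on average. Thus 12.7% of OPC peaks lacked a peak in this list of the same cell type, and 11.6% lacked an NPC peak. The share of OPC-alone peaks against NPC was therefore no larger than within the cell type. The order went the other way in the early part of the lists and at equal list length. At equal length 86.8% of OPC peaks had an OPC_NT peak and 84.3% an NPC peak. In the first 10% of the OPC_NT list 9 of 7779 peaks lacked an OPC peak (0.116%), and in the last 10% 60.7% did. Chromosome 17 had 17.7% of its OPC_NT peaks without an OPC peak and chromosome 13 had 11.6%.

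The comparison of OPC_NT with OPC_Insulator asks which CTCF sites are absent from cells that the sample's name ties to an insulator. The labels do not name the targeted site; the region around Pdgfra was chosen from general knowledge of the study. Between the start of Scfd2 and the end of Kit (chromosome 5, 74204816 to 75656722) the 4 lists together held 75 sites: 59 in NPC, 48 in OPC, 62 in OPC_NT and 34 in OPC_Insulator. Sites present in NPC, OPC and OPC_NT numbered 41, and 12 of these had no OPC_Insulator peak. That lay near the share over all chromosomes compared, where 17406 of 63167 such sites had none (27.6%). Of the 41 sites, 12 also stood in the first 20% of the OPC_NT list, and 2 of these had no OPC_Insulator peak, both at Pdgfra. One spans 75209923 to 75210189, between genes, its near edge 11.7 kb beyond the end of Pdgfra that faces Kit. It stood at place 14372 in NPC, 14838 in OPC and 13765 in OPC_NT, and the nearest OPC_Insulator peak centre lay 4638 bp away. Among 1996 sites of the same 3 lists within 1000 places of it in OPC_NT, this site included, 14 were absent from OPC_Insulator (0.701%, interval 0.384 to 1.17). The other spans 75156266 to 75156533, within the annotated span of Pdgfra and 4.9 kb from its Scfd2-facing end, at place 3511 in NPC, 3121 in OPC and 9527 in OPC_NT. Of 2001 like-placed sites, again with the site itself included, 9 were absent (0.45%, interval 0.206 to 0.852). This second site has OPC_Insulator peaks on both sides, at 75155652 to 75155948 and 75157087 to 75157383, and its centre lies 600 bp from the nearest of them; the OPC_Insulator list holds 4 pairs of peaks closer than 2 of its peak lengths and the OPC_NT list 92. The remaining 10 of these early sites of the region, among them 75157087 to 75157384 within Pdgfra and 75238419 to 75238715, were present in all 4 lists. A single site in the region, 75199703 to 75199999, 1.6 kb past Pdgfra, was in the OPC_Insulator list alone, at place 38642.

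The OPC_Insulator list was the shortest, which sets the genome-wide background. Its peaks overlapped 47203 of 77783 OPC_NT peaks (60.7%, interval 60.3 to 61.0), while OPC_NT peaks overlapped 97.4% of the OPC_Insulator peaks. Absent sites were late sites: of the sites in NPC, OPC and OPC_NT, 0.297% of those in the first 10% of the OPC_NT list were absent from OPC_Insulator and 91.3% of those in the last 10%. In the first 20% of the list 61 of 15522 were absent (0.393%, interval 0.301 to 0.505). The same count was 7 of 15468 for sites absent from OPC alone (0.0453%) and 16 of 15477 for NPC alone (0.103%). Of the 61 sites, 52 had an OPC_Insulator peak centre within 1 kb and 9 did not. The site beyond Pdgfra is number 5 by place among those 9. The others lie within the spans of Cdh13, a cadherin (place 3087), Iqsec1 (9149), the apoptosis adaptor gene Fadd (12288) and Myc, a growth regulator (14668), and between genes near Ptma (4587), Cbx5 (14590), Fxyd2 (14955) and Actb (15146). Next in order came sites near Cops8, Cbx5 and Tex35. The site in Fadd lies 0.8 kb from a gene end and the site in Myc 0.2 kb.

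**Figure D2:**
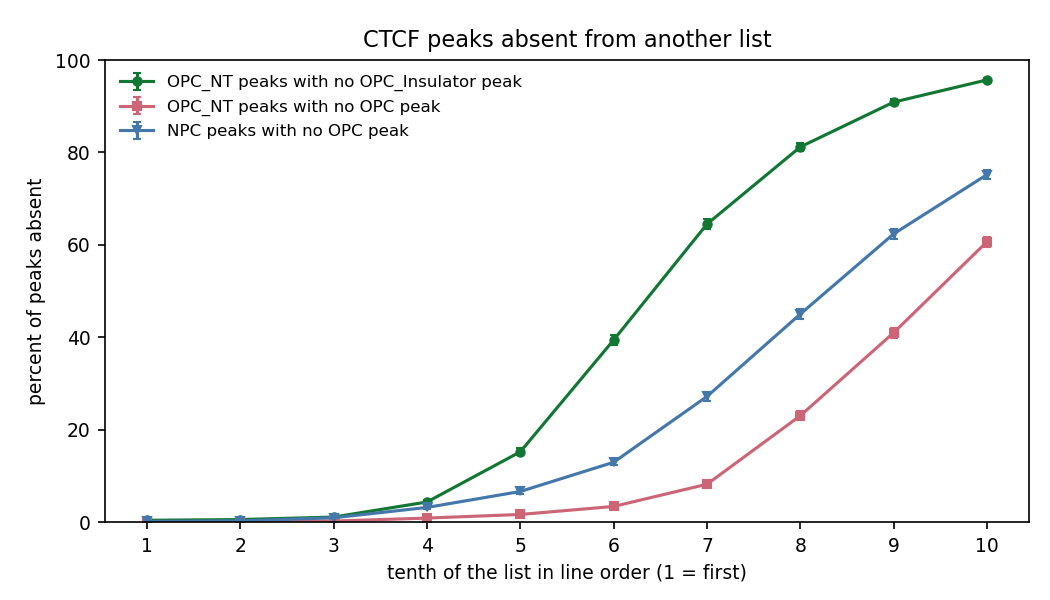
Percent of CTCF peaks absent from another list (y axis) for each 10% of the list in line order (x axis), with 95% exact intervals, for OPC_NT peaks against OPC_Insulator, OPC_NT peaks against OPC, and NPC peaks against OPC. Absence is under 2 percent at the first 3 points of each curve and reaches 95.7%, 60.7% and 75.2% in the last.

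The comparison of H3K27ac in NPC and OPC asks which genes carry acetylation in 1 of the cell types. The 3 lists with the largest mean difference toward OPC were astrocyte, Notch pathway and oligodendrocyte progenitor genes, followed by neural crest and stem cell genes. Astrocyte genes had 4.84 kb more acetylated length per gene in OPC within 20 kb of their ends, Notch pathway genes 3.60 kb more and oligodendrocyte progenitor genes 2.34 kb more. Cholesterol synthesis genes (-2.18 kb) and endothelial genes (-1.88 kb) had less. Of 21631 protein-coding genes, 10243 had a region within 1 kb of an end in both cell types, 1025 in OPC alone, 561 in NPC alone and 9802 in neither. Genes in 1 cell type alone were thus 64.6% OPC alone. Of all NPC regions 60.4% overlapped an OPC region (interval 59.98 to 60.9), and 66.2% of OPC regions overlapped an NPC region (interval 65.7 to 66.7). Long regions were shared: 191 of 193 NPC regions of 10 kb or more had an OPC region, and all 155 such OPC regions had an NPC region. Under 1 kb, 31.3% of NPC and 37.0% of OPC regions were shared.

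The gene with the largest difference in length among those with OPC acetylation alone was Myt1, a zinc finger factor of the oligodendrocyte lineage, with 23.2 kb acetylated in OPC and 5.19 kb in NPC. Sez6, a neuronal surface gene, had 22.5 and 8.10 kb, Ndrg2, an astrocyte-enriched gene, 13.4 and 1.44 kb, and Aqp4, the astrocyte water channel, 14.3 and 2.54 kb. The other 8 were Capn9, Tex33, Pla2g7, Fmod, Acss1, Spata3, Micall1 and S100a3, with 11.1 to 16.8 kb more in OPC. Windows of 20 kb also take in regions of neighbouring genes. On the NPC side the list held Cdkn1a, the p53-induced cell cycle inhibitor p21, with 14.8 kb in NPC and 1.27 kb in OPC, and Hic1, a transcriptional repressor, with 14.9 and 5.58 kb. Adam19 had 21.9 and 5.01 kb, the cytokine gene Il34 25.9 and 8.90 kb, and Dgkz 26.4 and 12.1 kb. Stpg4 had the largest difference, -29.4 kb, followed by Rfx8 at -18.3 kb; Cep41, 9430069I07Rik, Tle6, Gm5820 and Gm46041 lay between -16.8 and -12.2 kb. Among the longest regions of 1 cell type alone were a 12.3 kb NPC region within the potassium channel gene Kcnc1 and OPC regions of 9.57 kb in Sez6 and 8.75 kb in Myt1.

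Of the 20 oligodendrocyte progenitor genes, 8 had acetylation at an end in both cell types, 4 in OPC alone and none in NPC alone, and their mean of 8.38 kb in OPC and 6.05 kb in NPC lay at the 99.7th percentile of 10000 random lists of like covered length. Sox10 was in OPC alone, with 16.3 kb in OPC and 3.89 kb in NPC, as were Gpr17, Lhfpl3 and C1ql1. Gpr17 had only 0.5 kb in OPC, about the shortest region length. Ptprz1 had 19.7 and 5.98 kb. Olig1 and Olig2, the lineage-defining factors, were acetylated in both, Olig2 with 14.3 kb in OPC and 15.7 kb in NPC. The myelin genes were less distinct (0.794 kb more in OPC, 89.7th percentile), with Ugt8a, Opalin and Nkx6-2 in OPC alone. Within 20 kb, however, Opalin had less in OPC (1.41 kb) than in NPC (1.78 kb). All 12 astrocyte genes were acetylated at an end in OPC and 5 of them in OPC alone (Gfap, Aqp4, Aldh1l1, S100b and Ntsr2), at the 99.97th percentile. Gfap, the astrocyte filament gene, had 9.14 kb in OPC and 1.80 kb in NPC. The word alone refers only to regions within 1 kb of an end. Within 20 kb, Aldh1l1 had 15.1 kb in NPC and 20.1 kb in OPC, and Ntsr2 11.8 and 12.6 kb. The neural crest and Schwann list (2.21 kb more, 99.9th percentile) includes Sox10, and Foxd3 and Pmp2 were also in OPC alone. The stem and progenitor list was not higher in NPC: its mean was 9.66 kb in OPC and 7.63 kb in NPC (98.9th percentile; 0.534 kb more in OPC and 87.3rd percentile with windows of 5 kb), with Sox1 and Prom1 among those in OPC alone, and Sox2 and Nes near equal (-0.24 and -0.65 kb). Notch1, Hes5 and Hes1 belong to both the stem list and the Notch list (99.9th percentile), so these 2 results are not independent. Notch1 had 36.6 kb in OPC and 21.9 kb in NPC, and Hes5 11.8 and 2.70 kb. In the Notch list Hey2 and Nrarp were in OPC alone, while Hes1 (-3.01 kb) and Heyl (-4.07 kb) went the other way. Median differences were 0.934 kb for the stem list and 1.95 kb for the Notch list. Neuronal genes averaged 2.20 kb in OPC and 1.35 kb in NPC (98.3rd percentile), and 7 of 18 were in OPC alone. These were Tubb3, Dcx, Syt1, Elavl3, Gad1, Gad2 and Dlx5. Among them Syt1 and Gad2 had only 0.5 kb in OPC, while Elavl3 had 7.52 kb.

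On the NPC side, 12 of 13 cholesterol synthesis genes were acetylated in both cell types and Fdft1, squalene synthase, in NPC alone. Srebf2, the transcription factor that drives the pathway, had 22.0 kb in NPC and 9.62 kb in OPC (list at the 0.45th percentile; -0.504 kb and 7.56th with windows of 5 kb). The endothelial list lay below all random lists with windows of 20 kb, but differed by -0.202 kb at the 5.78th percentile with windows of 5 kb. Only Emcn had a region at an end in NPC (alone) and none of the 9 genes had one in OPC; within 20 kb Tek had 9.05 and 2.01 kb. Of 10 p53 and cell cycle inhibitor genes, Cdkn1a, Cdkn2b and Bbc3, which encodes the pro-apoptotic protein PUMA, were in NPC alone and none in OPC alone, while Trp53 had 18.2 kb in OPC and 10.4 kb in NPC. The list's mean difference was -1.83 kb (6.56th percentile; 2.08th with windows of 5 kb and 32.9th with 50 kb), with Cdkn1a at -13.5 kb. At the Cdkn2a locus (5.9th percentile; 0.33rd with windows of 5 kb and 12.8th with 50 kb) Cdkn2a was acetylated in both, with 6.43 kb in NPC and 5.61 kb in OPC, Mtap in both with 5.44 and 2.48 kb, and Dmrta1 in neither. With random lists drawn from the same chromosomes, the Cdkn2a locus lay at the 14.7th percentile, the cholesterol list at 0.59 and the oligodendrocyte progenitor list at 99.8.

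At the Pdgfra locus, OPC had 12 regions covering 24.4 kb between the end of Pdgfra and the start of Kit, and NPC had 3 covering 4.87 kb. The longest OPC region without NPC counterpart there spans 75220355 to 75227428 (7.07 kb), its centre 25.7 kb from Pdgfra. Within Pdgfra OPC had 1 region, 75155618 to 75157164 (1.55 kb), and NPC none; this region takes in the CTCF site at 75156266. Another OPC region, 75210070 to 75210699, overlaps the CTCF site at 75209923. No region lay within 1 kb of an end of Pdgfra in either list. Kit and Scfd2 had a region at an end in OPC alone, Fip1l1 and Chic2 in both, and Lnx1, Gsx2, Kdr and Pdgfra in neither. The 8 genes of the locus averaged 3.86 kb in OPC and 2.17 kb in NPC (99.1st percentile), and differed by 0.509 kb at the 85.0th percentile with windows of 5 kb. The locus was chosen from general knowledge of the study, so its list is no independent choice. Neighbouring genes share parts of their windows here and at the Cdkn2a locus, whereas the genes of random lists are scattered, so these genes are not separate measurements and the percentiles can be too extreme.

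Within the Hox clusters the direction differed along the genes. Hoxa3 and Hoxb3 were acetylated at an end in NPC alone, and Hoxb2 had 12.2 kb in NPC and 1.93 kb in OPC. Within 20 kb, however, Hoxa3 had 25.4 kb in NPC and 19.4 kb in OPC, and Hoxb3 14.3 and 5.0 kb. Hoxa7, Hoxa10, Hoxa13, Hoxc6, Hoxd3, Hoxd8 and Hoxd9 were acetylated at an end in OPC alone. Hoxd3 had 6.70 kb in OPC and Hoxd8 5.45 kb, both with none in NPC, while Hoxa7 had 5.32 kb in OPC and 4.26 kb in NPC. The 34 genes together differed by 0.169 kb (58.4th percentile), and their windows overlap, so they are not separate measurements. Differences for other lists were 1.11 kb for the Hedgehog pathway (87.7th percentile), 0.985 kb for receptor tyrosine kinases and growth factors (90.9), 0.523 kb for forebrain patterning (85.6), 0.421 kb for mesoderm and endoderm (74.9), 0.301 kb for pluripotent stem cell genes (75.7), 0.128 kb for mesenchymal genes (49.0), 0.068 kb for the protocadherins (59.2), -0.016 kb for imprinted loci (37.5), -0.354 kb for interferon response (19.8, with a median of 0.446 kb) and -0.715 kb for microglia and blood (10.1). In these lists Erbb4 had 15.8 kb in OPC and 4.65 kb in NPC, and Spry4, a feedback inhibitor of receptor signalling, 7.86 and 16.2 kb. Nanog, Gata6, Foxa2, Snai2, Prrx1, Lum, Pcdhac2 and Ifit3 were in OPC alone, and Col3a1 and Bst2 in NPC alone. Within 20 kb, however, Lum had less in OPC (0.5 kb) than in NPC (0.65 kb). Of 15 housekeeping genes 14 were acetylated in both, with equal means of 7.15 kb. H3K27ac regions followed the chromosome pattern of CTCF: X had 860 regions in OPC and 1264 in NPC, and chromosome 18 had 1259 and 1574, whereas chromosome 13 had 1873 and 1823. On the 10 chromosomes near the median, 574 genes were in OPC alone and 296 in NPC alone.

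**Figure D3:**
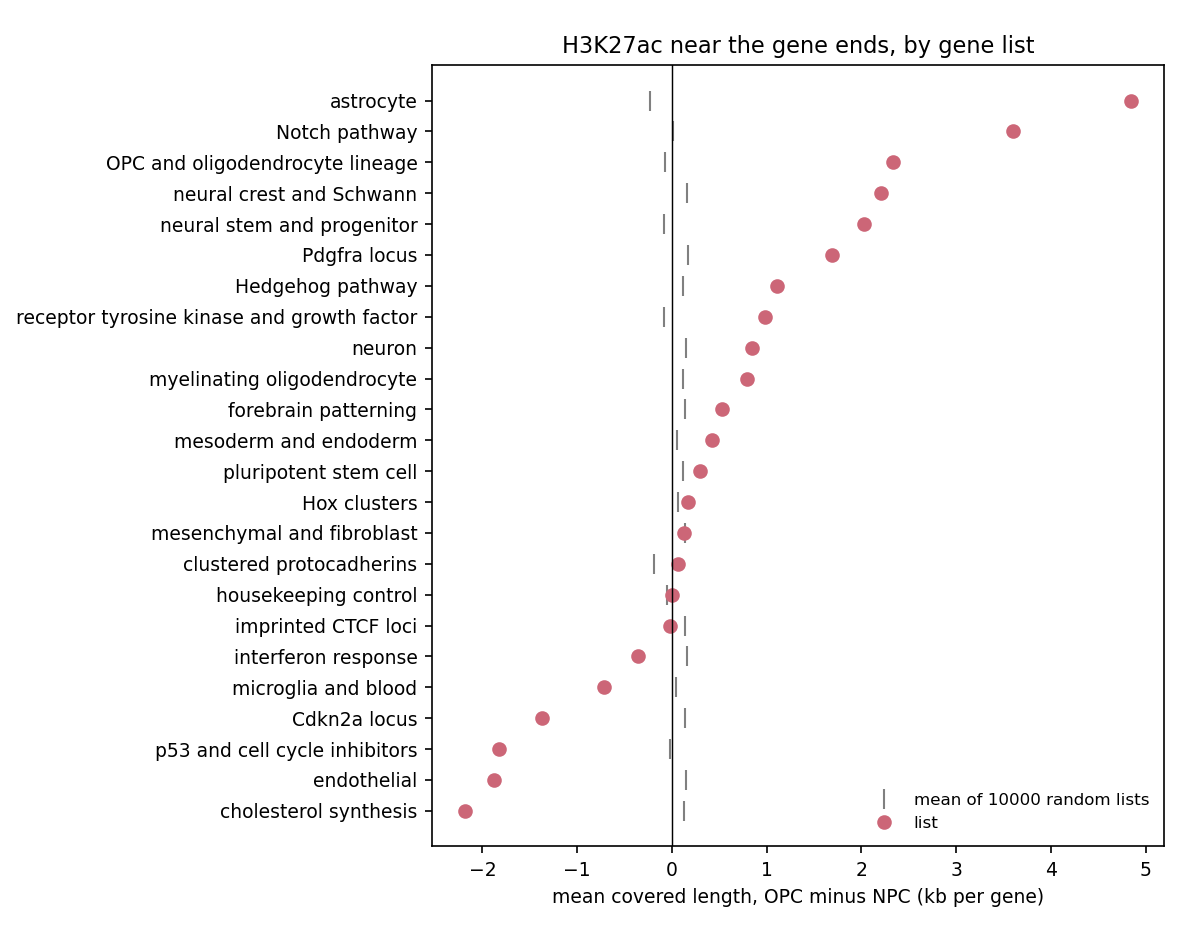
Mean difference in H3K27ac-covered length within 20 kb of the gene ends, OPC minus NPC in kb per gene (x axis), for 24 gene lists (y axis; filled circles), with the mean of 10000 random lists of like covered length (grey ticks). Astrocyte genes lie at 4.84 kb and cholesterol synthesis genes at -2.18 kb; each point is 1 pair of libraries and carries no error.

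CTCF peaks found in the NPC or the OPC list alone were compared with the acetylated regions of the same cell type. Of 8863 OPC-alone CTCF peaks, 36.4% overlapped an OPC H3K27ac region (interval 35.4 to 37.4), against 14.7% of the 67840 shared OPC peaks (interval 14.46 to 14.996). Of the same OPC-alone peaks, 30.9% overlapped an NPC region (interval 29.9 to 31.9). A further 6.63% overlapped an OPC region while the peak itself overlapped no NPC region (interval 6.12 to 7.17, shared peaks 3.44%). The OPC region can still meet an NPC region elsewhere along its length. Of 20692 NPC-alone CTCF peaks, 10.8% overlapped an NPC region (interval 10.4 to 11.2), against 14.1% of the shared NPC peaks (interval 13.9 to 14.4). Of the NPC-alone peaks, 4.22% overlapped an NPC region while the peak itself overlapped no OPC region (interval 3.95 to 4.50, shared peaks 2.68%).

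Human and mouse NPC H3K27ac lists were compared by number and length alone, since the human list is on build hg19 and no human annotation was used here. The human list had 1.34 times as many regions and 1.72 times the covered length. Its median region was 1577 bp long, against 1318 bp in mouse, and 795 regions (1.42%, interval 1.32 to 1.52) reached 10 kb, against 193 in mouse (0.461%, interval 0.398 to 0.53). The longest human regions were 44.2 kb on chromosome 2 (69338325 to 69382486), 40.0 kb on chromosome 6 and 38.1 kb on chromosome 11, and the longest mouse region was 47364 bp. Both lists had the same shortest length, 501 bp, at 15.6% of human and 18.8% of mouse regions.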

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

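The comparisons among mouse lists left out the Y chromosome. No control sample exists for it, so its peaks stand here only because each count is above 3, the limit that a count of 0 allows. That rule decides what is listed and does not measure signal on Y. No difference between groups was tested. On Y the mouse CTCF lists had 54 peaks in NPC, 71 in OPC, 70 in OPC_NT and 55 in OPC_Insulator. The mouse H3K27ac lists had 4 in NPC and 9 in OPC, of which 1 and 4 lay before 90 Mb. Of the CTCF peaks, 35 in NPC, 53 in OPC, 52 in OPC_NT and 38 in OPC_Insulator lay before 90 Mb, outside the far end of the chromosome.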

How the results depend on the processing

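Alternatives by line order, by chromosome and with regions anywhere in the gene were chosen after seeing the data. The planned ones by score were not run, since every score is 1, and the planned human promoter window was not run without a human annotation. With an overlap of at least 50% of the shorter peak, 76.3% of NPC CTCF peaks had an OPC peak, 88.1% of OPC peaks an NPC peak and 86.9% of OPC peaks an OPC_NT peak. With centres within 1 kb these shares were 77.9%, 90.1% and 89.5%, and 61.9% of OPC_NT peaks had an OPC_Insulator peak; of the early shared sites 0.0579% were then absent from OPC_Insulator, 1 of them at Pdgfra (the site beyond it), since that rule accepts a peak next to the site. In the first 50% of each list the shares were 80.4%, 92.8%, 93.0% and 62.0%, 0.297% of the early shared sites were absent and 0 at Pdgfra, because both Pdgfra sites then stand outside the first 20%. With lists of equal length by line order, NPC and OPC shared 84.3% each way, OPC peaks were in OPC_NT in 86.8% (above their share in NPC, as in the first 50% and unlike in the main setting) and OPC_NT peaks in OPC_Insulator in 88.2%, and 1 early Pdgfra site was absent, since the other stands outside the first 20%. On the 10 chromosomes near the median ratio the NPC and OPC shares were 79.3% and 87.9%. Human regions covered 1.78 times the mouse length in the first 50% of each list and 1.61 times at equal list length. OPC-alone CTCF peaks were within H3K27ac in 33.5% in the first 50% of the lists; NPC-alone peaks were in 9.92%, and in 10.1% by peak centre. Where no cause is named, the cause was not tested. Counts of genes with acetylation in OPC alone ran from 994 to 1107 and in NPC alone from 495 to 676 over 5 alternatives, the 1107 with regions anywhere in the gene. All 16 lists that differed by 0.5 kb or more kept their sign over 4 alternatives; 5 of the other lists changed sign in at least 1. Size and percentile were less stable. Of 120 list values 61 moved, 8 of them percentiles and the others mean lengths. Lengths change with the size of the window by construction, so this count by itself is no measure of stability. With windows of 5 kb the Notch list went from 3.60 to 1.68 kb but from percentile 99.9 only to 99.8. With windows of 5 kb the percentile went from 98.9 to 87.3 for the stem list, 99.1 to 85.0 for the Pdgfra locus, 0.45 to 7.56 for cholesterol and 0.0 to 5.78 for endothelial genes; with 50 kb the p53 list went from 6.56 to 32.9. The unknown depth limits every statement on late peaks, where a peak missing from a list can lie just under its threshold.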

Other observations

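The tests of peak absence at Pdgfra by place and distance and all tests of the chromosome pattern were chosen after the result was seen; the neighbour test for the site within Pdgfra and the p53 target test were written before.

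Acetylation of p53 target genes differed beyond the named Cdkn1a and Bbc3. A list of 24 other p53 targets, written before their values were looked at, had less acetylated length in OPC at 15 genes and more at 8. Trp53inp1 had 9.36 kb in NPC and an OPC minus NPC difference of -5.59 kb, and Phlda3 had 7.10 kb and a difference of -5.45 kb. Gdf15, Sesn2, Plk2 and Ccng1 were likewise lower in OPC. Pmaip1 and Plk3 had a region at an end in NPC alone, and Tigar in OPC alone. Btg2 went the other way, with 18.6 kb more in OPC. With windows of 20 kb, these targets as a class averaged less acetylated length in the OPC library. Their mean difference of -0.765 kb lay at percentile 2.73 of random lists of like covered length. The median was -0.634 kb and the mean of random lists 0.153 kb. With windows of 5 and 50 kb, added later, the list lay at percentiles 0.04 and 16.7. At 50 kb its mean was -0.735 kb, while the housekeeping list differed by -0.816 kb (26.5th percentile). Activity of p53 itself was not measured. The result rests on 1 library per cell type, and different growth media, culture stress or culture age stay open as untested.

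Absence of the CTCF site beyond Pdgfra (75209923 to 75210189) from the OPC_Insulator list is hard to place on the shorter list: 0.701% of like-placed sites were absent. Hiding by a neighbouring peak is also argued against, since the nearest OPC_Insulator peak centre lay 4638 bp away. For the site within Pdgfra (75156266 to 75156533), the share of absent like-placed sites was 0.45%, but hiding by a neighbour may account for its absence. Of 30 early sites with an OPC_NT neighbour closer than 2 OPC_Insulator peak lengths, 13 were absent (43.3%, interval 25.5 to 62.6). Of 15492 early sites without one, 48 were absent (0.31%). The site itself is counted among the 30 and the 13, and each Pdgfra site is counted among its like-placed sites. The labels do not name the targeted site, so deliberate change of the site beyond Pdgfra remains an open, untested hypothesis, and reads over the site in more than 1 culture would test it.

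Whole chromosomes differed in their number of peaks between NPC and OPC: 8 chromosomes (4, 11, 12, 14, 15, 16, 18 and X) lay 0.15 or more (log2) from the median ratio for CTCF, 2 above and 6 below. An effect of the CTCF precipitation alone is argued against, since 100% of the 8 had the same sign in H3K27ac, and so is regulation of single domains, since 100% of 53 windows of 20 Mb with 100 or more NPC peaks had the sign of their chromosome. Gene density as the whole cause is argued against. Of the 7 among them with another chromosome within 0.5 genes per Mb, 4 (57.1%) differed beyond counting error from the nearest in density. These were chromosomes 4, 14, 15 and 16, and 16 differed from 13 by -0.43. Chromosome 13 was the nearest for both 14 and 16. Its own ratio to NPC was 0.124 in OPC but 0.002 in OPC_NT, where 16 lay at -0.26, a smaller gap. All 8 chromosomes kept their sign with OPC_NT in place of OPC, but both ratios are to the same NPC list, so this is no independent check. As a part of the cause, gene density stays open, since 12, 18 and X are alike in density and ratio. It explained 0.21 of the variance over 20 chromosomes (95% interval 0.0004 to 0.561). A different number of copies of these chromosomes in the cultures is a candidate explanation that could not be tested from peak lists, and the difference between the cell types stays open as well; read depth per chromosome would test it.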
